A study of Homo sapiens with 2 samples.

How the data were processed

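The series holds 2 RNA sequencing libraries of A549 cells, 1 of cells stably transduced with an empty retroviral vector and 1 of cells stably transduced with ATOH8, grouped by the treatment label. Per the labels' protocols, RNA was harvested with Trizol and libraries were made from total RNA with a standard Illumina preparation. The submitters' processing notes name CASAVA, HISAT2 and Cufflinks 2.2.1 and the build hg38 (GRCh38), without saying which step each did. The gene annotation release, the strand setting, filters on reads and the read depth are not given in the sources used here. FPKM scales each gene by transcript length and by the library's total, so a rise in a few abundant transcripts lowers the values of the others, and the FPKM keep no count from which a counting error could be computed.

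The authors deposited 1 table of FPKM per library, with gene identifier, symbol and locus, per the file headers. These tables list no 0, so an unlisted gene can be at 0 or lack an estimate. MT-CO1, at 13096 FPKM in the vector file and unlisted in the ATOH8 file, shows that absence cannot be read as 0. Genes listed in 1 file only (2154 in the vector file, 2058 in the ATOH8 file) were therefore left out of the folds. The authors also deposited a table of their own comparison with a log2 ratio, a p-value and a q-value per gene, per the file headers. Its 2747 genes had q-values of at most 0.05 and absolute log2 ratios of at least 1.00, and 19 of them had a ratio to 0, which the file writes as an extreme number. With 1 library per group, those p-values compare the 2 libraries and not the conditions. This table's other 2 columns of per-library FPKM carry names that match no sample label and were not used.

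The FPKM tables were joined by gene identifier and rows sharing a symbol were then summed, giving 18786 symbols with a value in both libraries. The log2 fold was log2(ATOH8 + 1) minus log2(vector + 1), with a pseudocount of 1, which understates the change of low genes. Genes with a mean FPKM of at least 1 were kept (12342 genes). No test was run between the groups, since 1 library per group gives no spread. Instead a rule of size (2-fold) was used, and each list's median log2 fold was placed among the medians of 10000 random lists of the same size, drawn within 20 bins of mean expression. A list stood apart when its median lay outside the central 95% of the random medians, and lists with fewer than 5 measured members were not placed. This describes the 2 libraries and is not a test of the conditions. Folds relative to the median gene subtract the median log2 fold of genes with a mean FPKM of at least 5.

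The 29 gene lists were fixed before the data were examined, as were the processing alternatives and the rule for named genes. The rule named ATOH8, the 10 genes with the largest positive and the 10 with the largest negative log2 fold among those with a mean FPKM of at least 5, 18 cell cycle genes, and up to 4 members of each list, those with the largest absolute fold (in the list's direction where it stood apart). Some genes that this rule names are not reported here. A further 11 lists were written after the leading genes had been seen and are reported among the other observations. One of them, of nuclear oxidative phosphorylation genes, was also used to look at the trend with GC content.

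GC content and length were taken from the longest transcript of each gene in GENCODE 29 (GRCh38), matched by gene identifier for 99.8% of the tested genes, and gene positions are those of GENCODE 29. Matching on GC content or length used 20 bins of that property with 5 expression bins. The GC correction subtracted a lowess curve (fraction 0.3) of log2 fold on GC content. GC-corrected folds were centred with the median log2 fold of genes with a mean FPKM of at least 1 (-0.30). The other relative folds used that of genes with a mean FPKM of at least 5 (-0.36), so the 2 baselines differ slightly. The locus string of 53.3% of the tested genes spanned at least 2 genes, for which the authors' estimates could split reads.

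The list procedure was tested on simulated libraries of 12313 genes with lists of 20 genes, 100 lists per setting. For a simulated comparison of ATOH8 with vector without a GC trend, 4 of 100 unchanged lists were placed below the range, 78 of 100 lists lowered by 0.5 on the log2 scale and 100 of 100 lowered by 1. With a simulated GC trend, 61 of 100 unchanged AT-rich lists were placed below the range when matched on expression, and 1 of 100 when matched on GC content. Simulated folds were drawn independently for each gene and list members at random. These rates therefore do not carry over to real lists, whose members can vary together. Alternatives were a pseudocount of 0.1 or 5, no filter or a mean FPKM of at least 5, centring on the median gene, TPM and upper quartile scaling, the highest row of a shared symbol, lists matched on length, the list mean, and lists without shared members. Alternatives added after seeing the data were the GC correction, matching on GC content, reading unlisted genes as 0, and leaving out mitochondrial genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.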

Results

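Gene expression was measured by RNA sequencing in A549 cells, an established human lung adenocarcinoma line. A culture had been stably transduced with an empty retroviral vector and another with a retrovirus carrying ATOH8, which encodes a basic helix-loop-helix transcription factor. The design held 1 library per group, so every difference below compares these 2 libraries, carries no error from replicates and has no p-value. The vector file listed 20966 genes with a summed FPKM of 540101, and the ATOH8 file listed 20870 genes with a summed FPKM of 502502. The read depth was not given in the sources used here, so no counting interval could be attached to a value. The series title names cell proliferation and cell cycle genes as the subject, and the comparison asked which genes differed between the ATOH8 and the vector library.

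ATOH8 itself (ENSG00000168874, a protein-coding gene at chromosome 2, 85751344 to 85788066, plus strand, GRCh38) was listed at 0.786 FPKM in the vector library and at 182 FPKM in the ATOH8 library. Its log2 fold was 6.68 on the log2(FPKM + 1) scale, the largest positive value among the genes with a mean FPKM of at least 5. The transduced gene therefore stood where the labels place it. FPKM values were summed over the gene, so transcripts of the transgene and of the endogenous locus were not told apart.

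Among 12342 genes with a mean FPKM of at least 1, 770 were at least 2-fold higher and 2340 at least 2-fold lower in the ATOH8 library. The median log2 fold of genes with a mean FPKM of at least 5 was -0.36. Measured relative to that median, 1579 genes were at least 2-fold higher and 1168 at least 2-fold lower, so the lower share was 75.2% with the FPKM as deposited and 42.5% after centring. With a GC correction, centred on genes with a mean FPKM of at least 1 (median -0.30), 1029 genes were at least 2-fold higher and 736 at least 2-fold lower. Of the 736, 474 were also at least 2-fold lower than the median gene without the correction. All folds from here on are log2 folds relative to the median gene unless stated otherwise, and GC-corrected folds keep the baseline of the correction. Mitochondrial transcripts made up 24.2% of the summed FPKM in the ATOH8 library and 14.4% in the vector library, with MT-CO1 left out of both because the ATOH8 file did not list it. The authors' deposited table of differential expression held 2747 genes, 827 marked up and 1920 marked down, each with a q-value under 0.05. Of the 2728 genes of the authors' deposited table whose identifier had a value in both libraries, 2728 had the same direction in the per-library FPKM. RN7SL1, marked up as a ratio to 0 in the authors' deposited table, was outside this count: it was listed under different identifiers at 101.9 FPKM in the vector and 35.9 FPKM in the ATOH8 library. The match in direction was fixed in advance, because the authors' log2 ratios are ratios of these same FPKM. It is therefore no independent evidence.

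The log2 folds also followed base composition. Across 12313 genes with a known transcript sequence, the Spearman correlation of the log2 fold as deposited with GC content was 0.55 and the Pearson correlation was 0.51, computed across genes, which are not independent replicates. The median log2 fold as deposited was -1.06 in the decile of lowest GC content and 0.27 in the decile of highest GC content. For this reason each gene list was compared with random lists matched on expression and again with random lists matched on GC content and expression.

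**Figure D1:**
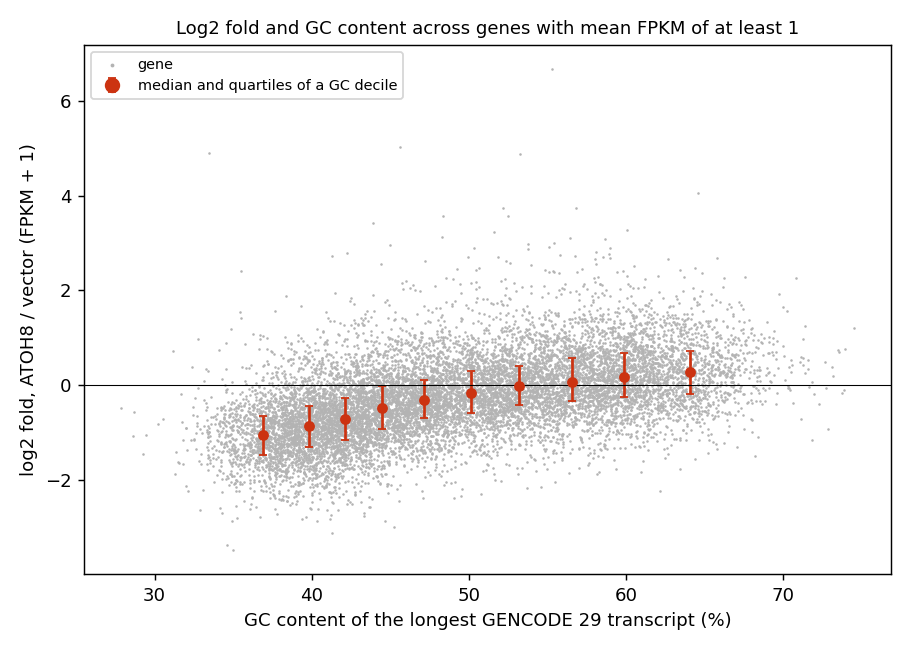
Log2 fold as deposited (ATOH8 over vector, FPKM + 1) against the GC content in percent of each gene's longest transcript; grey points are genes with a mean FPKM of at least 1, red points and bars are the median and quartiles of each GC decile. The decile medians run from -1.06 at the lowest GC content to 0.27 at the highest.

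Among the genes furthest above the vector library, the leading genes after ATOH8 itself were CXCL1 (1.19 against 70.8 FPKM, vector against ATOH8) and CXCL8 (0.748 against 50.8 FPKM), which encode neutrophil-attracting chemokines. CFB, a complement factor, stood at 0.279 and 36.4 FPKM, and MUC5B, a secreted airway mucin, at 1.25 and 36.5 FPKM. LCN2 (0.297 and 16.4 FPKM), SLPI (4.02 and 66.3 FPKM), DEFB1 (0.853 and 20.9 FPKM) and SERPINA3 (0.576 and 17.6 FPKM) encode proteins of mucosal defence or the acute phase. TXNIP, a thioredoxin-binding protein, was at 0.217 and 11.95 FPKM. The genes furthest below were led by the HSP90 co-chaperone CHORDC1 (71.4 and 5.45 FPKM), the neurotensin gene NTS (80.8 and 6.90 FPKM), the nucleolar protein gene NOP58 (66.5 and 6.68 FPKM) and HSP90AA1 (794 and 97.7 FPKM), an HSP90 chaperone. PBK, a mitotic kinase gene, was at 63.9 and 7.81 FPKM, MAD2L1, of the spindle checkpoint, at 35.3 and 4.12 FPKM, and KIAA1524 at 17.5 and 1.52 FPKM. TRA2A (37.8 and 4.42 FPKM) and HNRNPR (129.9 and 17.6 FPKM) encode RNA-binding proteins of splicing, and the remaining gene of the 10 was CTD-2116N17.1 (30.3 and 3.29 FPKM). The median GC content was 39.9% for these 10 lowest genes, 52.3% for the 10 highest and 48.5% over all tested genes. All 20, with ATOH8 among them, stayed at least 2-fold apart in the same direction after a GC correction. All 20 were also in the authors' deposited table. They were picked for the largest folds in the same FPKM, so neither result is an independent check. For 10 of the 20, CFB, MUC5B, DEFB1, SERPINA3 and HSP90AA1 among them, the file's locus spanned another gene, so reads could have been split between neighbours.

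Genes of DNA replication, the G1/S transition and mitosis were lower in the ATOH8 library as groups. Of 32 genes of the replication machinery, 20 were at least 2-fold lower and 0 at least 2-fold higher, with a median of -1.30. MCM10 (14.7 against 1.32 FPKM), the polymerase subunit gene POLE2 (14.5 against 1.59 FPKM), TIPIN and the clamp loader gene RFC3 had values of -2.40, -2.22, -2.12 and -2.08. Of 30 G1/S and E2F target genes, 13 were at least 2-fold lower and 0 higher, with a median of -0.93, led by DSCC1 (-2.39), the replication licensing gene CDC6 (-2.10) and UHRF1 (-1.80). Of 40 G2/M and mitosis genes, 21 were at least 2-fold lower and 0 higher, with a median of -1.05, led by MAD2L1 (-2.47), ECT2 (-2.06), TTK (-1.82) and TOP2A (-1.68). Of 29 genes of homologous recombination and the Fanconi pathway, 19 were at least 2-fold lower and 0 higher, with a median of -1.26, led by RBBP8 (-2.12), EXO1 (-2.10), BLM (-1.92) and RAD54B (-1.87). None of 10000 random lists matched on expression was as low as any of these 4 medians, and the same held for 10000 lists matched on GC content and expression. In the authors' deposited table, 25 of the replication genes, 15 of the G1/S genes, 24 of the mitosis genes and 24 of the repair genes were marked down and 0 of them up. The mitosis and repair lists were AT-rich, with a median GC content of 42.9% for mitosis and 41.4% for repair genes. After the GC correction the number at least 2-fold lower was 10 for mitosis, 12 for repair, 24 for replication and 18 for G1/S genes.

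Of 18 cell cycle genes chosen in advance, 17 were measured, 14 of them lay below the median gene and 6 were at least 2-fold below it. CDK1, the mitotic kinase, was at 92.9 FPKM in the vector and 21.9 FPKM in the ATOH8 library (-1.67), TOP2A at 109 and 25.8 FPKM, MCM2, of the replicative helicase, at 40.1 and 10.1 FPKM (-1.53), and CCNA2, cyclin A2, at 32.6 and 10.0 FPKM (-1.25). E2F1 was at 17.9 and 5.52 FPKM (-1.18), and PCNA, the sliding clamp, at 300.6 and 108.6 FPKM (-1.10). CCNB1 (-0.98), CDK2 (-0.93), CCNE2 (-0.74), MKI67 (-0.69), CCND1 (-0.38), CDK6 (-0.14) and CCNE1 (-0.14) were closer to the median gene, and MYC (-0.01) and CDK4 (0.02) lay on it. CDK1, TOP2A, MCM2 and PCNA were marked down in the authors' deposited table with q-values of 0.00641, 0.00107, 0.00558 and 0.0386, whereas E2F1 and CDK2 were not in it. After GC correction 5 of the 17 were at least 2-fold below the baseline of the correction. CDK1 (-0.996) and CCNA2 (-0.90) no longer were, CDK2 (-1.19) came to be, and CCNE2 moved to -0.06.

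CDKN1A, which encodes the CDK inhibitor p21 (ENSG00000124762, chromosome 6, 36676460 to 36687339, plus strand, GRCh38), was at 32.0 FPKM in the vector library and 194 FPKM in the ATOH8 library, a value of 2.92 relative to the median gene and 2.44 after GC correction. The authors' deposited table marked it up with a q-value of 0.00018. CDKN1B, which encodes p27, was at 22.3 and 28.1 FPKM (0.68). CDKN2B was listed only in the ATOH8 file, at 0.00844 FPKM, and CDKN2A only in the vector file, at 0.131 FPKM. The 9 measured CDK inhibitor and pocket protein genes went both ways: CDKN1A stood highest, and RBL1 (-1.53), CDKN3 (-1.21) and RB1 (-0.85) stood below the median gene. Their median of 0.60 was at percentile 94.1 of the random lists. The 24 p53 target genes had a median of 0.30 at percentile 91.8, with CDKN1A and BBC3 (4.23 and 18.8 FPKM, 2.28) above and PMAIP1 (-0.99) and MDM2 (-0.70) below. Of the 24, 15 lay above the median gene and 9 below it, and 4 were at least 2-fold higher and 0 at least 2-fold lower. With the FPKM as deposited, 11 were higher and 13 lower in the ATOH8 library. Of these, 3 were at least 2-fold higher and 3, PMAIP1, MDM2 and TP53I3, at least 2-fold lower. The balance of this list therefore depended on the centring. The authors marked CDKN1A and BBC3 up and MDM2 down. The 9 replication-dependent histone genes with a mean FPKM of at least 1 also lay inside the random range, at a median of 0.40 and percentile 79.96. The rest of that list was below this level or did not have a value in both libraries, so the placement does not speak for histone genes as a class. HIST2H2BE stood at 1.28, and HIST1H2BK, HIST1H2BD and HIST1H4H at -0.66, -0.55 and -0.08.

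**Figure D2:**
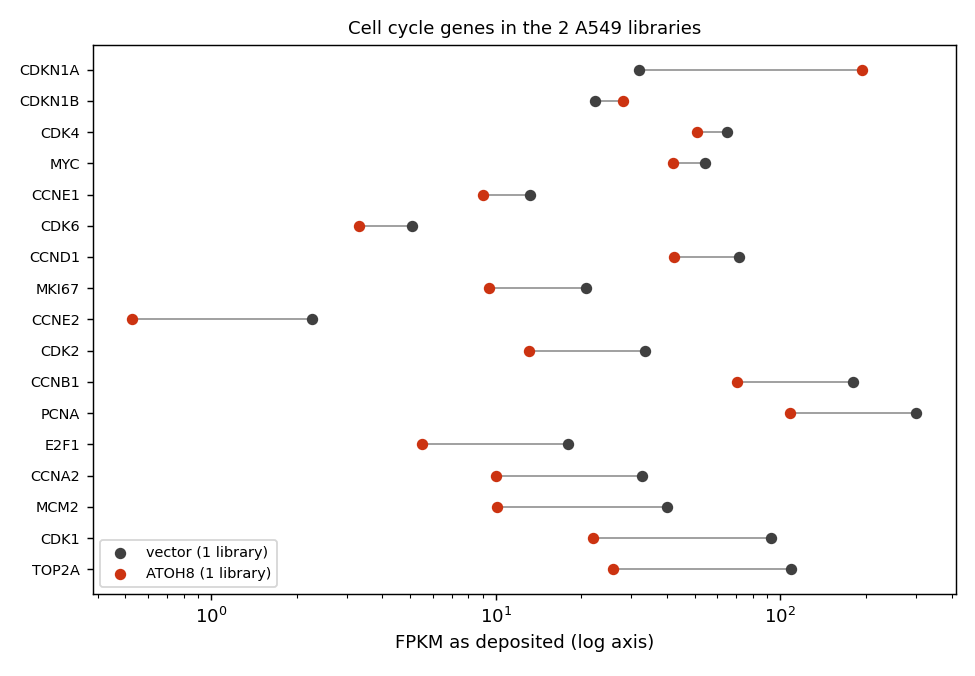
FPKM as deposited, on a log axis, of 17 cell cycle genes in the vector library (black) and the ATOH8 library (red), 1 library each, ordered by the log2 fold of FPKM + 1. CDKN1A and CDKN1B lie higher in the ATOH8 library, and the other genes lie lower.

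Ribosome biogenesis and chaperone genes were also lower. Of 30 genes of the MYC and ribosome biogenesis list, 15 were at least 2-fold lower and 0 higher (median -0.996), led by NOP58 (-2.78), WDR43 (-1.74), the nucleolin gene NCL (313 and 79.95 FPKM, -1.60) and RRS1 (-1.50). The 38 cytosolic ribosomal protein genes lay inside the random range at a median of 0.09 and percentile 45.9, with RPL7 (-1.08), RPL6 (-0.62), RPL14 (-0.48) and RPL22 (-0.48) furthest from the median gene. Of 21 heat shock and cytosolic chaperone genes, 8 were at least 2-fold lower and 3 higher (median -0.69), led by CHORDC1 (-3.13), HSP90AA1 (-2.65), HSPH1 (-2.26) and DNAJB4 (-1.86). The 3 higher members, picked out after their values were seen, were the small heat shock protein genes HSPB1 (237 and 847 FPKM) and CRYAB (0.71 and 3.53 FPKM) and the collagen chaperone gene SERPINH1 (22.3 and 40.4 FPKM). The medians of the ribosome biogenesis and chaperone lists lay below the central 95% of random lists under both ways of matching.

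Cytokine and antigen presentation genes were higher in the ATOH8 library. Of 19 NF-kB, cytokine and senescence secretory genes, 11 were at least 2-fold higher and 0 lower, with a median of 1.78, and 0 of 10000 random lists were as high under either matching. CXCL1 (5.39), CXCL8 (5.25), the chemokine gene CCL20 (0.204 and 5.38 FPKM, 2.77) and TNFAIP2 (57.6 and 289 FPKM, 2.66) led the list. Members that encode NF-kB subunits or feedback regulators, picked out after their values were seen, were spread out: TNFAIP3 stood at 1.78, RELB at 1.14, NFKB2 at 0.64, NFKB1 at 0.12 and BIRC3 at -0.27, with NFKBIA on the median gene. Of the 19, 9 were marked up and 0 down in the authors' deposited table. Of 13 antigen presentation genes, 6 were at least 2-fold higher and 0 lower (median 0.94), with HLA-DMA at 1.82, HLA-E at 1.80, HLA-B at 1.56 and HLA-F at 1.48. The 16 type I interferon response genes lay inside the random range at a median of 0.40 and percentile 88.9, with STAT2 at 1.37, IFIT5 at -0.92, OAS1 at -0.80 and HERC5 at -0.77. Relative to the median gene, 3 of the 16 were at least 2-fold higher, STAT2, IRF9 and IFI6, and 0 at least 2-fold lower. With the FPKM as deposited, STAT2 alone was at least 2-fold higher, and 3, IFIT5, OAS1 and HERC5, were at least 2-fold lower. The balance of this list therefore depended on the centring. The authors marked OAS1 and HERC5 down and IRF9 up.

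Lists of TGF-beta response, mesenchymal and lung lineage genes were higher as well. Of 20 BMP, TGF-beta and SMAD response genes, 8 were at least 2-fold higher and 0 lower (median 0.87), among them TGFBI (331 and 1388 FPKM, 2.42), ID3 (1.69) and BMP2 (1.55). Of 14 measured mesenchymal genes of the epithelial-mesenchymal transition, 7 were at least 2-fold higher and 0 lower (median 1.08). They were led by CDH2, which encodes N-cadherin (1.34 and 17.2 FPKM, 3.32), the fibronectin gene FN1 (58.6 and 411 FPKM, 3.15), ACTA2 (3.06) and COL1A1 (2.42). The members within 2-fold of the median gene were TWIST2 (0.75), VIM (0.52), TWIST1 (0.45), S100A4 (0.43), TAGLN (0.37), ZEB1 (-0.41) and THBS1 (-0.41). The epithelial list was not lower: of 15 junction and keratin genes, 5 were at least 2-fold higher and 0 lower (median 0.62). CLDN2 stood at 2.93, CLDN4 at 2.39, KRT80 at 2.34 and CDH1, which encodes E-cadherin, at 15.4 and 54.1 FPKM (2.11). The 3 members below the median gene were CLDN1 (-0.81), OCLN (-0.50) and TJP1 (-0.455). With the FPKM as deposited, 6 of the 15 were lower in the ATOH8 library, and 1 of them, CLDN1, was at least 2-fold lower. Of 9 alveolar and lung lineage genes, 5 were at least 2-fold higher and 0 lower (median 1.43). Those furthest up were the mucin genes MUC5B (4.42) and MUC5AC (2.24), CEACAM6 (2.40) and the water channel gene AQP3 (1.86). The other member at least 2-fold higher was the surfactant lipid transporter gene ABCA3 (1.43), and no surfactant protein gene had a mean FPKM of at least 1. The TGF-beta, mesenchymal and lung lineage lists lay above the central 95% of random lists under both ways of matching, and after the GC correction their medians were 0.50, 0.68 and 0.88. The junction list, with a median of 0.15 after the correction, did so when matched on expression (percentile 98.8) and not when matched on GC content (percentile 96.6).

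Metabolic and signalling lists were mixed. Of 27 glycolysis and hypoxia genes, 7 were at least 2-fold higher and 0 lower (median 0.47), with CA9, a carbonic anhydrase gene (5.39 and 60.6 FPKM, 3.63), ALDOC (3.08), ANGPTL4 (2.10) and NDRG1 (2.06) leading. The list stood at percentile 98.3 when matched on expression and 96.3 when matched on GC content, and its median was 0.20 after the GC correction. The WNT list (18 genes, median 0.63, percentile 99.4, DKK3 at 2.42, CD44 at 1.29, TCF7L2 at 1.02 and NKD2 at 0.92) lay above the random range under both matchings, at percentile 97.7 under the second, but inside it after the GC correction, where its median was 0.14. The Notch list (14 genes, median 0.58, HES1 at 1.99, NOTCH3 at 1.69, HES2 at 1.51 and NOTCH2 at 1.20) had a percentile of 97.6 when matched on expression and 72.8 when matched on GC content. Lists inside the central 95% of random lists were those of NRF2 targets (median 0.08, GCLC at -1.72 and ABCC3 at 2.28), cholesterol and fatty acid synthesis (0.31, HMGCS1 at -1.07 and TM7SF2 at 1.85), ATF4 and unfolded protein response (-0.11, PSAT1 at -2.08 and MTHFD2 at -1.39), immediate-early and MAPK feedback genes (0.45, JUNB at 1.92), apoptosis regulators (0.12, BMF at 2.46) and stemness genes (-0.37, BMI1 at -1.90, at the lower edge with 251 of 10000 random lists at or below it). The 12 mitochondrially encoded protein genes with a value in both libraries had a median of 1.14, above the random range under both matchings, with MT-ND5 at 956 and 3077 FPKM and MT-ND4L at 2588 and 6904 FPKM. In all, 6 of the 27 lists with at least 5 measured members lay below and 10 above the central 95% of random lists matched on expression, and 6 below and 7 above when matched on GC content. Lists of independently drawn genes would give 1.35 outside. Members of a real list can vary together and some lists share members, so the number that chance would give here is not known.

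Few markers of other cell types reached a mean FPKM of 1, and the 4 that did were higher in the ATOH8 library. Of the blood cell list, CD68 (2.14 and 15.4 FPKM), CD14 (1.12 and 9.14 FPKM) and ITGAM (0.706 and 1.32 FPKM) had a mean FPKM of at least 1, and the pan-leukocyte gene PTPRC was listed only in the ATOH8 file, at 0.0111 FPKM. Of the fibroblast and endothelial list, only COL1A1 had a mean FPKM of at least 1, at 2.16 and 12.2 FPKM, and this gene is also a member of the mesenchymal list.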

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

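The scaling and blood cell tests, the question of culture differences and the rescaling without mitochondrial genes were chosen after the results were seen, and the test within ribosomal protein and oxidative phosphorylation genes replaced a test over all genes once the trend over all genes was known, but before its own result was computed. With at least 1 FPKM, 20 genes were listed in the ATOH8 file only and 22 in the vector file only, HTR2B and FBXL21 among the latter, both marked down as a ratio to 0 in the authors' deposited table. Of the 20 in the ATOH8 file, 9 were protein-coding. They drew attention because the folds do not use them and the vector file did not list them. Among the 9, IL1B, an inflammatory cytokine gene, stood at 1.88 FPKM, LTB, of the tumour necrosis factor family, at 2.16 FPKM, IFITM1, an interferon-induced gene, at 2.99 FPKM, and CLEC4E at 1.37 FPKM. PARK2 stood at 1.11, RP11-542C16.2 at 1.51, RP4-539M6.19 at 2.70, RP11-603J24.9 at 3.51 and CTD-2550O8.5 at 8.79 FPKM. In the authors' deposited table IL1B, LTB, IFITM1 and CLEC4E were marked up as a ratio to 0, with q-values of 0.0390, 0.0150, 0.0407 and 0.0245.

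The first pattern weighed was the lower level of the replication, G1/S, mitosis and repair lists. GC content as the whole cause is argued against, since 0 of 10000 random lists matched on GC content and expression were as low as any of the 4 medians, and transcript length likewise, with 0 of 10000 lists. A uniform scaling of the libraries is argued against by values already given, since all 4 medians lay below the median gene. Under 3 other scalings the highest of the 4 medians was -0.93. That is the G1/S median after centring, known before this test was chosen, so the test adds nothing to it. GC content may still account for part of the size in the mitosis and repair lists. Their medians were -1.05 for mitosis and -1.26 for repair genes before the GC correction and -0.88 and -0.87 after it. The replication median was -1.30 before and -1.29 after, and the G1/S median -0.93 before and -1.11 after. Corrected values have a slightly different baseline (-0.30 in place of -0.36), so small differences between before and after are not read. A difference between the 2 cultures other than ATOH8, such as density or passage, cannot be told apart from an effect of ATOH8 with 1 library per group.

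The second pattern, noticed in the data, was that log2 folds were higher at higher GC content. A bias of library preparation or sequencing may be its source. Within 115 ribosomal protein and oxidative phosphorylation genes, taken as groups of related function, the Spearman correlation was 0.31 (95% bootstrap interval 0.13 to 0.47). That value was just above the bound of 0.3 set for such a bias. The interval comes from resampling genes of these 2 libraries, which are not independent of each other, and covers no difference between replicate libraries. The correlation was 0.50 in the 38 ribosomal protein genes and 0.27 in the 77 oxidative phosphorylation genes. The oxidative phosphorylation list was written after the leading genes had been seen. With the members of the cell cycle, repair and ribosome biogenesis lists left out, the correlation over the other 12111 genes was 0.55. The trend therefore did not rest on those list members. Leaving out so few of 12313 genes could hardly have changed it. Other AT-rich genes of these functions stayed among the 12111, so their share in the trend is not settled. A biological change in AT-rich transcripts, for example through their stability, was not tested and stays open beside the technical one.

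The third pattern was the higher level of the NF-kB, cytokine and senescence secretory list. GC content is argued against, with 0 of 10000 lists matched on GC content as high, and CXCL8, at 33.4% GC, went against the trend. Blood cells in the culture are argued against by a summed FPKM of 0.147 in the ATOH8 library, which rests on PTPRC and LAPTM5, since CD52 and TYROBP were not listed there and cannot be read as 0. The macrophage markers CD68 (2.14 against 15.4 FPKM) and CD14 (1.12 against 9.14 FPKM) were nevertheless higher there. A secretory response to ATOH8, to cell cycle arrest or to a difference in culture density each stays open and untested.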

How the results depend on the processing

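The settings named as GC correction, matching on GC content, unlisted genes as 0 and mitochondrial genes left out were chosen after seeing the data. The ATOH8 level had a log2 fold between 5.02 and 7.68 under every setting run on it. The count of genes at least 2-fold higher, 770 with the FPKM as deposited, was 287 with a pseudocount of 5, 477 with a mean FPKM of at least 5, 1579 when centred on the median gene, 1452 under upper quartile scaling, 509 after the GC correction (median left at its deposited value) and 1226 with mitochondrial genes left out. The count of genes at least 2-fold lower, 2340 as deposited, was 1066 with a pseudocount of 5, 1168 when centred and 1262 under upper quartile scaling. With mitochondrial genes left out and the rest rescaled to the same total, the median log2 fold moved from -0.30 to -0.10. After centring, 1168 of the 2340 lower genes were still at least 2-fold lower, and 1158 of the 2340 were so after the GC correction without centring. The 6 lists that lay below the random range did so under every setting run, and so did the higher placement of the TGF-beta, mesenchymal, lung lineage, NF-kB and antigen presentation lists. The higher placement of the Notch list was lost under the GC correction, where its median of -0.30 without centring equalled that of all genes (-0.30), and under 6 other settings; the cause was not tested. The junction, hypoxia and WNT lists came inside the random range after the GC correction, whereas the CDK inhibitor and p53 target lists came to lie above it and the ATF4 list below it. Matched on GC content, the junction and hypoxia lists also came inside. With a mean FPKM of at least 5 the WNT and junction lists came inside and the interferon and immediate-early lists above, and without a filter the WNT list came inside and the interferon list above. By the list mean, the p53 target and immediate-early lists lay above the range. Directions in the authors' deposited table matched the FPKM for 2452 of 2452 genes with a mean FPKM of at least 1. This was fixed in advance, since the authors' ratios are ratios of the same FPKM, and it is no check of the results. No replicate could be left out, and no paired analysis was possible because each group held 1 library and the labels give no replicate numbers. Depth limits every value here, since the FPKM give no count and low genes have an unknown error.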

Other observations

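All lists in this part were written after the leading genes had been seen, so they describe the same 2 libraries and are not independent evidence. Of 15 measured acute phase, complement and epithelial defence genes, 13 were at least 2-fold higher and 0 lower relative to the median gene (median 2.76, above all 10000 random lists under both matchings). Beside CFB, LCN2, SLPI and DEFB1, the list held genes picked out after their values were seen, the complement genes C3 (1.10 against 17.1 FPKM), C1R (5.95 against 35.7 FPKM) and C1S (11.9 against 54.3 FPKM), whereas the fibrinogen gene FGB was at 34.2 and 23.2 FPKM. Of 20 laminin, integrin and hemidesmosome genes, 10 were at least 2-fold higher and 0 lower (median 0.96; 5 higher and a median of 0.49 after the GC correction), with LAMB3 at 4.25 and 34.8 FPKM and ITGB4 at 10.1 and 52.9 FPKM. The 28 lysosomal genes had a median of 0.74, with 8 at least 2-fold higher (5 after the GC correction), among them GAA (18.2 and 57.9 FPKM), CTSD (83.2 and 189 FPKM) and PSAP (245 and 509 FPKM). Both lists lay above all random lists under both matchings. Of 3 measured metallothionein genes, which encode metal-binding proteins, MT1X was at 28.9 and 236 FPKM, MT2A at 47.6 and 186 FPKM and MT1F at 2.95 and 2.67 FPKM.

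Of 25 hnRNP and SR splicing factors, 15 were at least 2-fold lower and 0 higher (median -1.20), with HNRNPR at -2.46, TRA2A at -2.48, SRSF7 at 104 and 20.9 FPKM and HNRNPA2B1 at 704 and 158 FPKM. This list was AT-rich, with a median GC content of 40.4%, and 9 of the 25 were at least 2-fold lower after the GC correction. The 29 nuclear pore and importin genes had a median of -0.88, with 10 at least 2-fold lower (-0.54 and 5 after the GC correction), and with XPO1, the main export receptor, at 121 and 22.1 FPKM. The 8 CCT chaperonin subunits had a median of -1.05, with CCT6A at 230 and 59.8 FPKM. The 31 proteasome subunits had a median of -0.71, with PSMD12 at -1.88, and the 20 aminoacyl-tRNA synthetases a median of -0.71, with TARS at 151 and 24.5 FPKM. All 5 of these lists lay below the random range under both matchings. The 28 translation initiation factors (median -0.52, EIF5 at 93.0 and 13.97 FPKM) lay below it when matched on expression and at percentile 2.60 when matched on GC content. The 77 nuclear oxidative phosphorylation genes had a median of 0.10, inside the range, with NDUFA5 at 40.2 and 14.2 FPKM and COX6C at 154 and 65.5 FPKM, while the mitochondrially encoded genes had a median of 1.14.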
